A study of Mus musculus with 24 samples.

How the data were processed

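The series holds 24 bulk RNA-seq libraries of neurons from adult mouse cortex, 6 in each of the subtypes EXC, PV, SST and VIP. Per the labels, tissue was dissociated with papain, and cells negative for the dye DAPI and positive for GFP or tdTomato, by reporter line, were sorted by fluorescence. RNA was then purified and its quality measured, and the purity of the sorts was tested by quantitative PCR. The labels give the sex and the sequencing pool of each library. They do not say how many animals contributed to a library, so each library was treated as 1 replicate, and replicates are numbered in the order of deposition.

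The authors aligned the reads to the mouse genome GRCm38 with GSNAP, whose version is not given in the sources used here. Per the file headers, the deposited counts are the numbers of reads that align uniquely to a gene model. The second deposited column holds size-factor-adjusted RPKM values computed by the authors. The counting program, the annotation release, the strand setting and the method behind the size factors are not given in the sources used here. For 5201 genes the ratio of count to RPKM was checked within each library after dividing out a factor per gene, and its largest spread was 2.05e-15 on the log2 scale. Counts were used for every value reported, and RPKM values for this check only.

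Each library lists 36528 genes by NCBI Gene number. Of these, 31049 were matched in RefSeq, which gave symbols and coordinates, and 78 more through GENCODE M21, which gave symbols. A symbol given by both sources was kept for the RefSeq gene only, so 31126 genes had a symbol. The 5402 genes without a symbol held 0.844% to 2.983% of the reads of a library; they stayed in the tests but are not named. Total counts had a median of 6012251.5 per library. A level of 10 CPM amounts to 15.5 reads in the library with the fewest reads, with a counting error of 25.4%, to 60.1 reads at the median depth (12.9%) and to 160 reads at the highest (7.91%). Counting intervals at 95% and the floor of 3 counts cover counting error only, not the spread between libraries. Chi-square tests of the counts of 60 pairs of libraries within a subtype gave at least 5.1 per degree of freedom, so no library was found to be a copy of another.

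Genes were filtered with filterByExpr by subtype, library sizes were scaled by TMM, and a model with terms for the 4 subtypes and for sex was fitted to all 24 libraries with edgeR 4.0.16 in R 4.3.3. Quasi-likelihood F tests were run for EXC against the mean of the other subtypes, for PV, SST and VIP each against the mean of the other GABA sorts, for the 6 pairs, for female against male, and for the 3 subtype-by-sex terms. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. The same test was run within POOL6188 for PV and EXC and within POOL7098 for SST and VIP. Printed folds are log2 fold changes with a standard error, except for genes close to 0 reads in a group, where the ratio of summed normalised reads is given with its counting interval. The standard error is the size of the change divided by the square root of its F statistic, not a separate estimate from the model. Principal components used the 2000 most variable genes on log2 CPM with a prior count of 2.

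For gene sets, 37 lists of neuron classes, other brain cells, cell state, receptors, channels, other functions and sex-linked genes were tested with camera at a preset correlation of 0.01, camera with an estimated correlation and fry in limma 3.58.1, with adjustment over the lists within a comparison. For each list the members called higher or lower were also counted, with p-values adjusted over all genes and over the list alone. A further 4 lists, of dentate granule cells, hippocampal pyramidal cells, ciliated ependymal cells and choroid plexus, were written after the data were examined. The tests, the 37 lists, the comparisons, the settings to vary and the rule for naming genes were chosen before the data were examined.

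That rule names, for each comparison of a subtype with a mean, the 10 genes with the largest positive and the 5 with the largest negative log2 fold change. It takes genes with an adjusted p under 0.05, at least 10 CPM on average in the higher subtype and no overlap between libraries, and skips predicted genes and genes without a symbol. Pvalb, Sst, Vip, Slc17a7, Gad1 and Gad2 are always eligible, as are up to 4 called members of each list by size of change and up to 1 member not called. For sex it names up to 10 genes by adjusted p, with Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Of the genes the rule names, only a part is described, and some are not reported here.

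The alternatives tried were DESeq2 1.42.0 with its Wald test, its size factors or upper-quartile factors in edgeR, no filter, a filter of at least 5 CPM in at least 6 libraries, the pool as a covariate, the fit without the 2 libraries alone of their subtype in their pool, robust empirical Bayes, no sex covariate, only the libraries compared, only 1 pool, and for sex no genes on X and Y. Fits without the 37 mitochondrial genes and without EXC replicate 3, EXC replicate 6, PV replicate 1 or PV replicate 6 were chosen after seeing the data. For each comparison, labels were also reassigned at random to give 40 assignments, the real one included. Relations between values across the 6 libraries of a subtype were tested by exact permutation. Each group of 6 libraries whose level, sum or library measure is reported was searched for a library far from the rest with Dixon's test (critical value 0.625); this includes the 7 gene levels for which only reads are printed.

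The procedure was tested on simulated data made from these counts, with 50 genes changed at each fold. The changed genes were drawn at random from genes above a minimum mean count. Of genes changed 2-fold it recovered 56% for EXC, 48% for PV, 66% for SST, 56% for VIP and 76% for sex, and of genes changed 4-fold at least 90%, with 6 to 10 false calls per comparison. Only 200 genes changed per simulated comparison, all others had the same mean level in every library, and no pool effect was simulated. The false calls therefore do not carry over to the subtype comparisons, where far more genes were called and pool follows subtype. Values were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Pseudocount alternatives, planned for normalised values only, were left out because the files hold counts.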

Results

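The series profiles neurons sorted by fluorescence from the cortex of adult mice by bulk RNA-seq, in 4 subtypes that the labels call EXC, PV, SST and VIP, with 6 libraries each. The labels do not spell these names out. EXC has 4 male and 2 female libraries, PV 3 and 3, SST 4 and 2, and VIP 2 and 4. Total read counts ran from 1548907 in PV replicate 6 to 15978459 in SST replicate 6. They averaged 6809687 ± 1530846 in EXC, 2862276 ± 1081037 in PV, 11788654 ± 3878361 in SST and 6061102 ± 1440213 in VIP (SD, n = 6 each). Genes with at least 1 read numbered 18968 ± 1189 in EXC, 16472 ± 993 in PV, 21294 ± 737 in SST and 20356 ± 1234 in VIP. The labels place all 6 PV and 5 EXC libraries in the sequencing pool POOL6188, EXC replicate 3 and 4 VIP libraries in POOL7099, 5 SST libraries and VIP replicates 1 and 3 in POOL7098, and SST replicate 5 in POOL7100. Most libraries of a subtype thus lie in 1 pool, and only PV with EXC, SST with VIP, and VIP with EXC share a pool. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples. Levels below are normalised CPM, given as the mean ± SD of the 6 libraries of a subtype.

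PV, SST and VIP each carried the namesake gene far above the other subtypes, and EXC, which has no namesake gene, had the highest Slc17a7. Pvalb, which encodes the calcium-binding protein parvalbumin (NCBI Gene 19293, GRCm38 chromosome 15, 78191112 to 78206400), stood at 201 ± 21.4 CPM in PV, against 1.33 ± 0.857 in EXC, 3.16 ± 1.66 in SST and 0.365 ± 0.331 in VIP. Sst, the somatostatin gene (20604, chromosome 16, 23889573 to 23891342), stood at 1160 ± 261 CPM in SST, against 26.0 ± 24.9 in EXC, 58.8 ± 51.8 in PV and 4.62 ± 6.56 in VIP. Vip, the gene of vasoactive intestinal peptide (22353, chromosome 10, 5639193 to 5647617), stood at 1730 ± 51.4 CPM in VIP, against 1.58 ± 2.13 in EXC, 0.756 ± 0.589 in PV and 1.40 ± 0.666 in SST. Slc17a7, which encodes the vesicular glutamate transporter VGLUT1 (72961, chromosome 7, 45163921 to 45176139), stood at 532 ± 214 CPM in EXC, against 19.5 ± 5.83 in PV, 42.5 ± 13.6 in SST and 7.43 ± 8.78 in VIP. The GABA synthesis gene Gad2 (14417, chromosome 2, 22621015 to 22693877) stood at 321 ± 155 CPM in EXC, 2280 ± 221 in PV, 4470 ± 688 in SST and 2840 ± 378 in VIP. Gad1 (14415, chromosome 2, 70561303 to 70602014) followed with 104 ± 32.2, 1290 ± 193, 838 ± 208 and 1240 ± 269 CPM. In a principal component analysis of 2000 genes the first 3 components held 35.5%, 28.3% and 13.4% of the variance. Mean profiles were closest for PV and SST (Pearson r across genes, which are not independent replicates, 0.915) and farthest for PV and VIP (0.837). The lowest correlation between libraries of the same subtype was 0.808 in EXC, 0.905 in PV, 0.957 in SST and 0.884 in VIP. Genes at least 2-fold higher than in each of the other subtypes, each past the test, numbered 772 in EXC, 501 in PV, 149 in SST and 645 in VIP.

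**Figure D1:**
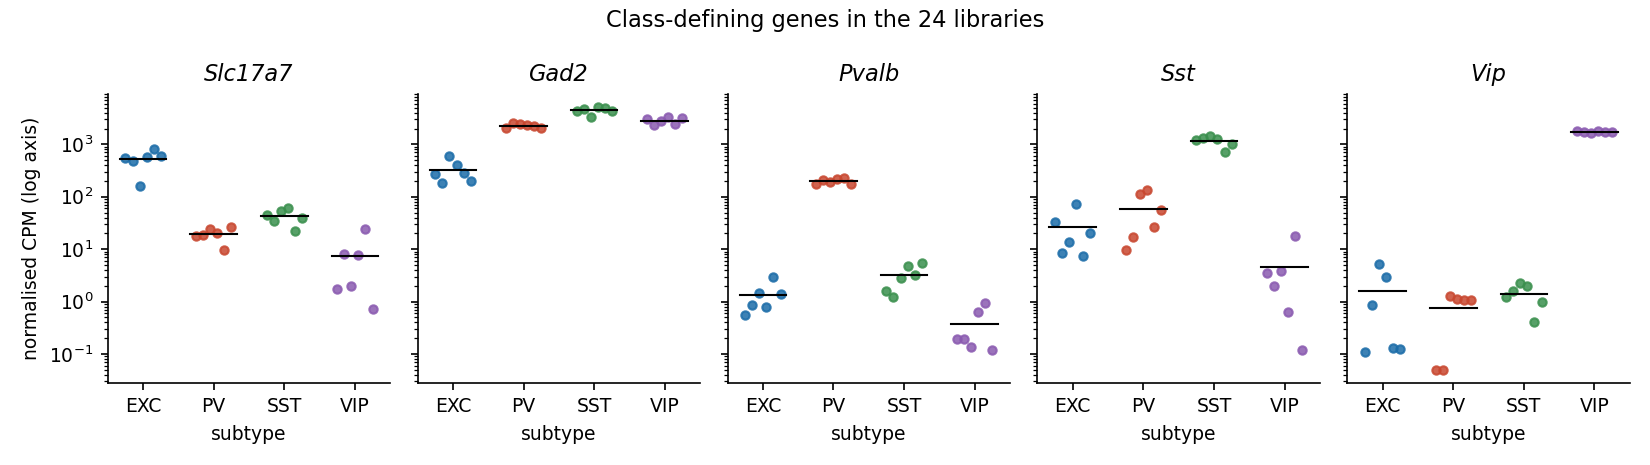
Normalised CPM of Slc17a7, Gad2, Pvalb, Sst and Vip on a log axis, with 1 point per library, 6 libraries per subtype and a line at each mean; values under 0.05 are drawn at 0.05. Pvalb averaged 201 CPM in PV, Sst 1160 in SST and Vip 1730 in VIP.

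EXC was compared with the mean of PV, SST and VIP to find the genes that set EXC apart from the other sorts. Excitatory neuron markers and postsynaptic density genes stood higher in EXC, and pan-GABAergic markers lower, while lists of single interneuron classes were mixed. Neurod2, a transcription factor of glutamatergic neurons, reached 236 ± 54.2 CPM in EXC (log2 fold change 6.34 ± 0.27 SE, adjusted p = 2.36e-16), and its relative Neurod1 rose by 6.12 ± 0.34 (adjusted p = 6.33e-14). Slc17a7 rose by 4.85 ± 0.35 (adjusted p = 6.68e-12). Of 19 measured excitatory neuron markers 18 were higher and 1 lower (camera adjusted p = 9.74e-19, and 0.00976 with an estimated correlation); Nptx1, a secreted pentraxin that clusters glutamate receptors, rose by 5.44 ± 0.26. Of 22 postsynaptic density genes 19 were higher and 0 lower, and 19 and 1 when adjusted over the list alone (camera adjusted p = 6e-12, 0.0241 with an estimated correlation). Among them were Nrgn, the calmodulin-binding neurogranin gene, with 4.55 ± 0.35, and Camk2a, a subunit of a calcium-dependent kinase, with 2.63 ± 0.20. Markers of cortical layers 5 and 6 were higher for 9 of 13 genes and lower for 1 (camera adjusted p = 2.64e-05, 0.0398 with an estimated correlation), with Crym at 4.41 ± 0.41 and Fezf2, a deep-layer transcription factor, at 3.73 ± 0.48.

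All 15 pan-GABAergic markers were lower in EXC (camera adjusted p = 1.91e-34, 1.38e-06 with an estimated correlation). Gad1 fell by 3.44 ± 0.19 and Gad2 fell by 3.29 ± 0.21 on the log2 scale. Dlx2, a homeobox gene of interneuron development, fell by 5.60 ± 0.38 and stood at 0.421 ± 0.540 CPM in EXC. Erbb4, the neuregulin receptor, fell by 4.64 ± 0.25. Genes of the medial ganglionic eminence lineage were lower for 9 of 10 and higher for 1 (camera adjusted p = 1.71e-10, 0.000609 with an estimated correlation). Of 15 PV interneuron markers 12 were lower and 1 higher (camera adjusted p = 1.85e-15, 0.000238 with an estimated correlation). VIP interneuron markers were lower for 9 of 14 and higher for 2 (camera adjusted p = 0.00407, 0.0504 with an estimated correlation). SST interneuron markers, lower for 7 of 15 and higher for 3, did not pass camera (adjusted p = 0.175). Genes of the caudal ganglionic eminence lineage, lower for 8 of 10 and higher for 2, did not either (0.175). Prox1, a member of this list, stood at 942 ± 103 CPM in EXC, against 8.41 ± 3.64 in PV, 9.26 ± 3.27 in SST and 1130 ± 39.6 in VIP. Neurogliaform and LAMP5 markers were higher for 4 of 9 and lower for 1 (camera adjusted p = 0.175). Btbd11 fell by 5.99 ± 0.20 to 3.32 ± 0.982 CPM, and Gjd2, which encodes the gap junction protein connexin 36, fell by 5.53 ± 0.37 to 0.849 ± 0.720 CPM. Pthlh, which encodes parathyroid hormone-related protein (19227, chromosome 6, 147252109 to 147264013), had 2 reads over the 6 EXC libraries against 3210 over the other 18, a ratio of 523 (95% counting interval 145 to 4320; adjusted p = 2.17e-13). Lrrc38, an auxiliary subunit of calcium-activated potassium channels, had 3 reads against 759, a ratio of 82.4 (28.1 to 400; adjusted p = 9.77e-12). Pvalb fell by 2.18 ± 0.38 and Vip fell by 3.22 ± 0.59.

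Of the 10 genes with the largest positive fold changes in EXC, 5 are genes known from hippocampal granule cells, a grouping made after their values were seen. C1ql2, a secreted synaptic organiser (226359, chromosome 1, 120340582 to 120343174), had 63.8 ± 17.5 CPM in EXC and a total of 8 reads over the other 18 libraries (ratio of summed normalised reads 1070, 95% counting interval 544 to 2490; adjusted p = 5.54e-19). Lct, the lactase gene, had 119 ± 55.0 CPM (ratio 546, 384 to 804; adjusted p = 2.92e-17), and Dsp, which encodes the junction protein desmoplakin, had 275 ± 69.5 CPM with a log2 fold change of 8.63 ± 0.33 (adjusted p = 3.27e-17). Tdo2, a tryptophan-degrading enzyme, had 16.0 ± 3.87 CPM (ratio 189, 105 to 381) and Smoc2, a matrix protein, 18.7 ± 6.63 CPM (ratio 44.3, 33.7 to 59.4). Summed, these 5 genes reached 492 ± 120 CPM in EXC and at most 8.59 CPM in any other library. A list of 12 further dentate granule cell genes was added after the data were examined. It leaves out known markers also high in another sort, such as Prox1, Calb1 and Pdyn. Prox1 stood at 942 ± 103 CPM in EXC and 1130 ± 39.6 in VIP, against 8.41 ± 3.64 in PV and 9.26 ± 3.27 in SST. Calb1 and Pdyn were higher in SST (376 ± 73 and 184 ± 40.4 CPM) than in EXC (142 ± 33.3 and 38.3 ± 16.8). All 12 listed genes were higher in EXC, a count set in part by that choice of genes. Their summed level was 3754 ± 386 CPM in EXC, against 1041 CPM in the highest library of another subtype. Also among the leading genes were Cd209a with 25.6 ± 16.1 CPM (ratio 413, 209 to 959), Ccnjl with 11.7 ± 4.25 (60.4, 40.1 to 95.2), Robo3, an axon guidance receptor, with 10.6 ± 9.80 (59.3, 37.9 to 98.1) and Slamf7 with 12.9 ± 10 (123, 72.7 to 227).

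Immediate early and stress genes were higher in EXC for 17 of 25 and lower for 1 (camera adjusted p = 2.97e-05), but with an estimated correlation the adjusted p was 0.145. Egr3 rose by 3.68 ± 0.27 and Arc, a synaptic activity-regulated gene, by 3.49 ± 0.39. Voltage-gated calcium channel genes were higher for 8 of 15 and lower for 2 (camera adjusted p = 0.000646; adjusted p = 0.0691 with an estimated correlation). Cacna1e, the pore of R-type channels, rose by 2.90 ± 0.10, and the auxiliary subunit gene Cacna2d2 fell by 3.06 ± 0.21. Genes for AMPA receptor auxiliary subunits were higher for 11 of 17 and lower for 3 (camera adjusted p = 0.000413; adjusted p = 0.25 with an estimated correlation). Neuropeptide precursor genes were lower for 14 of 21 and higher for 4 (camera adjusted p = 0.00903; adjusted p = 0.206 with an estimated correlation). Grm2, a metabotropic glutamate receptor gene, rose by 4.28 ± 0.24, and Gabra5, a GABA-A receptor subunit gene, by 3.11 ± 0.13. Nuclear oxidative phosphorylation genes were lower for 16 of 28 and higher for 0, and lower for 17 when adjusted over the list alone (camera adjusted p = 0.000575; adjusted p = 0.553 with an estimated correlation). That mean includes PV at 7712 CPM over these genes; EXC, with 3082 ± 1050 CPM, lay between VIP (2770 ± 667) and SST (3766 ± 400).

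Single markers of several other brain cells passed the test in EXC, while none of these lists passed camera. All 9 measured oligodendrocyte markers were higher, among them the myelin gene Mobp with 2.85 ± 0.61 (camera adjusted p = 0.11). Their summed level averaged 1314 ± 1432 CPM in EXC and came to 3022 CPM in replicate 2, 3238 CPM in replicate 6 and 88.6 CPM in replicate 3. Astrocyte markers were higher for 7 of 12, and for 8 when adjusted over the list alone (camera adjusted p = 0.175), microglia markers for 8 of 12, and for 10 over the list alone (camera adjusted p = 0.106), and mural cell markers for 7 of 11 (camera adjusted p = 0.175). Endothelial markers were higher for 4 of 7 (camera adjusted p = 0.385). Both measured oligodendrocyte precursor markers were lower (camera adjusted p = 0.175), as were 3 of 9 striatal markers, with 0 higher (camera adjusted p = 0.175). EXC replicate 3 had the lowest summed level of excitatory markers in EXC, 3049 CPM against 5841 CPM or more in the other 5, and the highest of GABAergic markers, 1074 CPM. Without that library the camera adjusted p of the oligodendrocyte list was 0.00805. With an estimated correlation the adjusted p was 0.665 for the oligodendrocyte list, 0.76 for astrocytes, 0.656 for microglia, 0.66 for mural cells and 0.802 for endothelium. The astrocyte sum came to 4695 CPM in EXC replicate 6; without that library 4 of 11 astrocyte markers were higher and 1 lower, and with the pool as a covariate 1 of 12 was higher and 2 lower.

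In all, 6330 of 14890 genes differed between EXC and the mean of the others at an adjusted p under 0.05, with 3641 higher and 2689 lower (edgeR quasi-likelihood test). The fit with the pool as a covariate called 2841 genes higher and 2997 lower. With the sequencing pool as a covariate C1ql2, Ccnjl and Robo3 lost their calls (adjusted p = 1) although their fitted changes stayed large, at 8.88, 6.08 and 7.63; that fit left their change undetermined. Fezf2 lost its call as its change shrank to 0.62 ± 1.29 (adjusted p = 0.737), and the fitted change of Mobp changed sign to -2.12 ± 1.22 (adjusted p = 0.17). The lower level of Sst (fell by 1.44 ± 0.55, adjusted p = 0.037) lost its call with pool as a covariate (-2.32 ± 1.05, adjusted p = 0.0818) and with robust empirical Bayes (-1.44, 0.0654). That call was also lost without EXC replicate 3 (-1.34, 0.0523) and without EXC replicate 6 (-1.4, 0.0654).

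**Figure D2:**
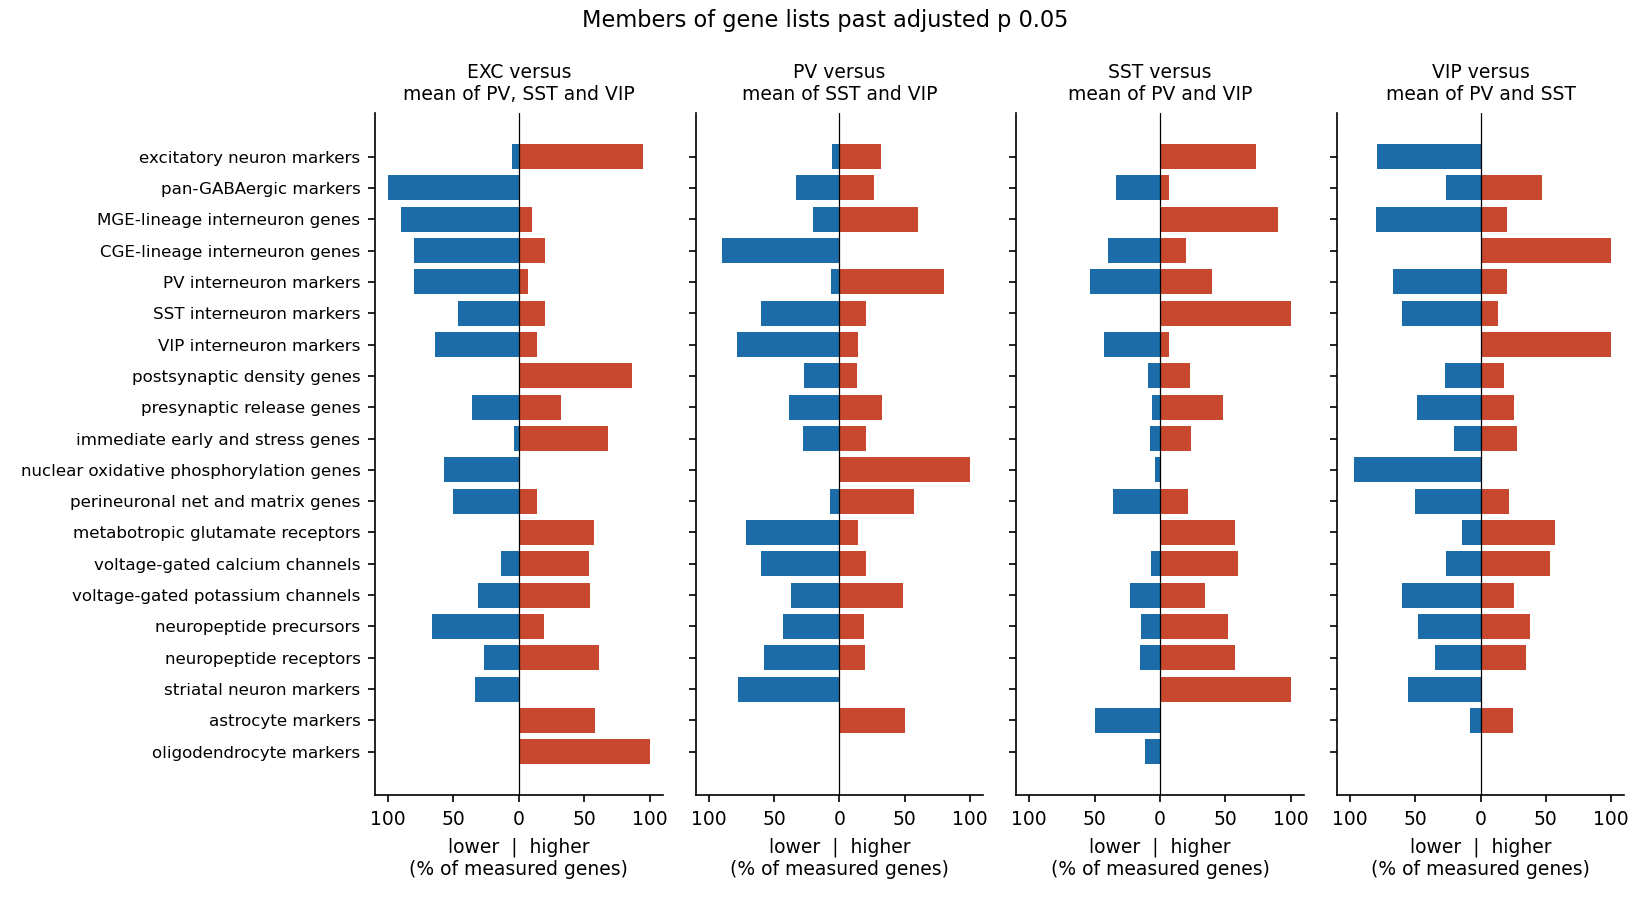
Share of the measured members of 20 gene lists that were higher (red, right) or lower (blue, left) at an adjusted p under 0.05, in percent, for each of the 4 comparisons of a subtype with the mean of others. All 28 nuclear oxidative phosphorylation genes were higher in PV and 27 were lower in VIP.

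PV was compared with the mean of SST and VIP, to find what sets PV apart from the other sorts rich in GABA synthesis genes. Its leading genes included Pvalb and genes of motile cilia, and genes of respiration were higher by smaller folds. Pvalb rose by 7.54 ± 0.30 (adjusted p = 3.4e-16). Syt2, the fast calcium sensor of transmitter release, rose by 6.16 ± 0.30 (adjusted p = 1.44e-14), Kcng4, a modifier of potassium channels, by 6.98 ± 0.56 to 29.1 ± 9.51 CPM, and Tac1, the substance P gene, by 4.58 ± 0.28. Akr1c18, a steroid-metabolising enzyme, had 22.6 ± 8.34 CPM in PV and 0 reads in VIP (ratio to both groups 25.2, 95% counting interval 20 to 32.1; adjusted p = 1.45e-07). Of 15 PV interneuron markers 12 were higher and 1 lower (camera adjusted p = 3.28e-27, 2.05e-05 with an estimated correlation). Genes of the medial ganglionic eminence lineage were higher for 6 of 10 and lower for 2 (camera adjusted p = 0.000108, 0.0122 with an estimated correlation), with the transcription factor gene Lhx6 at 3.48 ± 0.28.

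Genes of the perineuronal net, the matrix coat of many parvalbumin neurons, and other matrix genes were higher for 8 of 14 and lower for 1, and 8 and 2 when adjusted over the list alone (camera adjusted p = 1.55e-08, 0.00068 with an estimated correlation). Acan, which encodes the net protein aggrecan, rose by 5.23 ± 0.54, Adamts15, a matrix protease, by 4.11 ± 0.23, and Mme, the peptidase neprilysin, by 3.80 ± 0.19. The delta opioid receptor gene Oprd1 rose by 5.37 ± 0.28, and Gabrd, which encodes the delta subunit of GABA-A receptors, by 4.85 ± 0.32. Frmpd2, a scaffold protein gene, had 14 ± 11 CPM in PV (ratio 71.9, 44.6 to 123; adjusted p = 7.06e-09).

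All 28 nuclear oxidative phosphorylation genes were higher in PV, with a median log2 fold change of 1.26 (camera adjusted p = 2.14e-16; adjusted p = 0.0895 with an estimated correlation). Cox6a2, a cytochrome c oxidase subunit, rose by 3.09 ± 0.36, Ndufb5, a subunit of respiratory complex I, by 1.80 ± 0.19 and Cox5a by 1.66 ± 0.23. Summed over the 28 genes the level was 7712 ± 652 CPM in PV, against 3082 ± 1050 in EXC, 3766 ± 400 in SST and 2770 ± 667 in VIP. Mitochondrially encoded genes took 35.1% ± 13.3 of the reads in PV, with a range of 14.4% to 52.9%, against 7.40% ± 2.60 in EXC, 6.41% ± 1.56 in SST and 9.65% ± 6.23 in VIP.

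**Figure D3:**
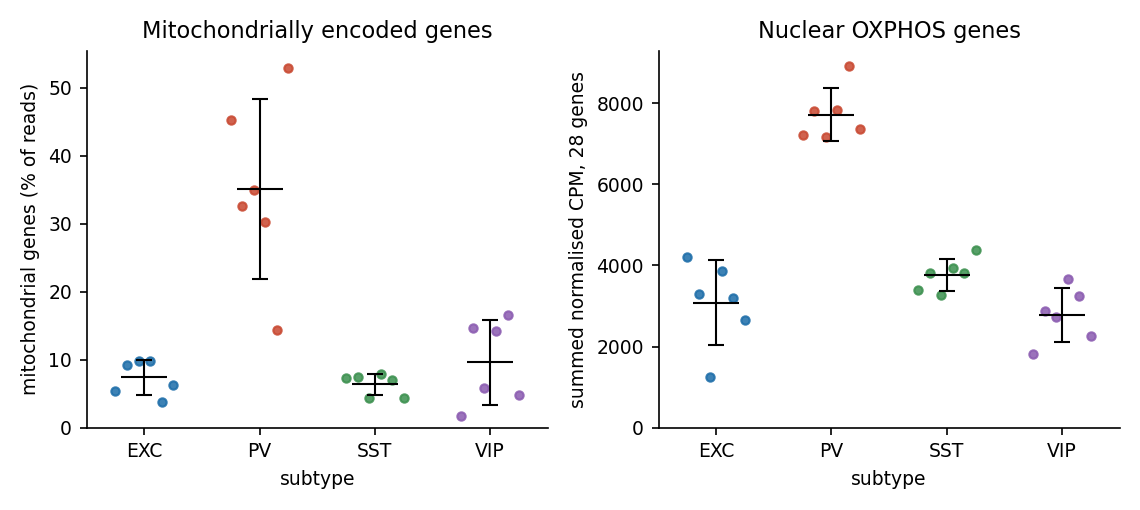
Left, share of reads from the 37 mitochondrially encoded genes in percent; right, summed normalised CPM of 28 nuclear oxidative phosphorylation genes (OXPHOS), with 1 point per library and the mean ± SD of 6 libraries per subtype. PV averaged 35.1% on the left and 7712 CPM on the right.

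Among the 10 leading genes of PV, 6 belong to motile cilia or ciliated cells, a grouping made after their values were seen. Stoml3 (229277, chromosome 3, 53488707 to 53508863) had 16.0 ± 6.24 CPM in PV and 0 reads in SST and VIP, which makes it at least 548-fold higher against a floor of 3 counts over those groups (adjusted p = 7.15e-09). Tmem212 had 14.3 ± 9.55 CPM (ratio 717, 95% counting interval 195 to 5970), Cfap161 22 ± 12 (124, 76.1 to 217), Ccdc153 17.5 ± 7.43 (137, 78.6 to 262), Ak7, an adenylate kinase of cilia, 27.9 ± 13.5 (90.3, 62.4 to 135) and Fam216b 10.4 ± 4.52 (184, 82.5 to 512). The largest adjusted p of these 6 genes was 7.15e-09. Summed, they reached 108 ± 48.6 CPM in PV, with a range of 40 to 174, and at most 1.69 CPM in any other library. All 11 measured members of a list of 14 further genes of ciliated ependymal cells, added after the data were examined, were higher in PV. Astrocyte markers were higher in PV for 6 of 12 and lower for 0 (camera adjusted p = 0.0254; adjusted p = 0.524 with an estimated correlation), with the water channel gene Aqp4 at 3.95 ± 0.56. Their summed level in PV, 713 ± 211 CPM, lay between that of SST (at most 429 CPM) and that of VIP (at least 1232 CPM), whose 12 libraries averaged 880 ± 571. With the pool as a covariate 0 were higher and 2 lower.

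Genes of the caudal ganglionic eminence lineage were lower in PV for 9 of 10 and higher for 0 (camera adjusted p = 1.77e-17, 2.27e-05 with an estimated correlation). VIP interneuron markers were lower for 11 of 14 and higher for 2, and lower for 12 when adjusted over the list alone (camera adjusted p = 6.81e-14, 3.67e-05 with an estimated correlation). Adarb2, an RNA-editing enzyme relative, fell by 6.69 ± 0.41, Htr3a, the serotonin-gated channel gene, fell by 5.07 ± 0.54, Crh, the corticotropin-releasing hormone gene, fell by 6.57 ± 0.44, and Calb2, the calretinin gene, fell by 6.53 ± 0.56. Fxyd6, a regulator of the sodium pump, fell by 7.79 ± 0.46 to 0.870 ± 0.878 CPM (adjusted p = 5.7e-13). Tac2, the neurokinin B gene, had 1 read over the 6 PV libraries and 18219 over SST and VIP (ratio 2170, 95% counting interval 390 to 85800; adjusted p = 4.6e-11). Plpp4 had 1 read against 1646 (ratio 196, 35.2 to 7760), Stk26 1 against 1431 (171, 30.6 to 6750) and Wnt7a, a secreted signal, 3 against 2796 (111, 38 to 539). Metabotropic glutamate receptor genes were lower for 5 of 7 and higher for 1 (camera adjusted p = 1.4e-05, 0.000847 with an estimated correlation); Grm8 fell by 3.95 ± 0.35 and Grm7 fell by 3.04 ± 0.28. Voltage-gated calcium channel genes were lower for 9 of 15 and higher for 3 (camera adjusted p = 1.36e-05, 0.0222 with an estimated correlation); Cacna2d3 fell by 3.96 ± 0.20 and Cacna1e fell by 2.63 ± 0.14. Neuropeptide receptor genes were lower for 15 of 26 and higher for 5 (camera adjusted p = 0.0123; adjusted p = 0.102 with an estimated correlation), and Npy1r, a neuropeptide Y receptor gene, fell by 4.99 ± 0.35. Gabra2 fell by 3.68 ± 0.33 and Vip fell by 5.81 ± 0.62. Gad2 fell by 0.65 ± 0.18 (adjusted p = 0.00611); Gad1 (0.34 ± 0.16, adjusted p = 0.0873), Slc17a7 (0.12 ± 0.44, adjusted p = 0.849) and Sst (-0.18 ± 0.57, adjusted p = 0.826) did not pass the test.

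In all, 6091 genes differed between PV and the mean of SST and VIP, 2868 higher and 3223 lower. With the sequencing pool as a covariate the count was 2729 (835 higher and 1894 lower), of which 1149 had been called without it. In that fit, whose link between POOL6188 and the others rests on EXC replicate 3, Stoml3, Tmem212, Cfap161, Ccdc153, Fam216b, Frmpd2 and Akr1c18 lost their calls (adjusted p = 1) with fitted changes of 7.18, 10.65, 6.64, 14.1, 8.79, 9.47 and 2.81, and Ak7 with 3.34 (adjusted p = 0.968); their change was left undetermined. Kcng4 (1.41 ± 8.24), Stk26 (-2.86 ± 1.44), Syt2 (3.05 ± 1.80), Adamts15 (2.77 ± 1.11), Gabrd (1.71 ± 0.76) and Lhx6 (2.15 ± 1.85) lost theirs with a smaller change and a wider error. Acan (1.46 ± 2.14), Ndufb5 (0.10 ± 0.47), Cox5a (0.32 ± 0.60) and Aqp4 (0.52 ± 1.52) lost theirs with a change below its error, and of the 28 oxidative phosphorylation genes 1 was called higher and 1 lower, with a median of -0.18 instead of 1.26. Gad2 (0.55 ± 0.37) and Cox6a2 (-1.85 ± 3.05) changed sign without a call. Slc17a7 changed sign to a called -3.42 ± 0.89 (adjusted p = 0.00904), and Gad1 gained a call (1.12 ± 0.39, adjusted p = 0.049).

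SST was compared with the mean of PV and VIP. Neuropeptide genes and markers of somatostatin neurons stood higher in SST, and so did genes known from striatal and excitatory neurons. Sst rose by 6.09 ± 0.56 (adjusted p = 3.93e-09). All 15 SST interneuron markers were higher (camera adjusted p = 4.06e-44, 4.5e-08 with an estimated correlation). Pdyn, the prodynorphin gene, rose by 7.24 ± 0.36 to 184 ± 40.4 CPM (adjusted p = 4.71e-14). Chodl, a membrane lectin gene of long-range somatostatin neurons, had 15.1 ± 3.09 CPM (ratio 23.4, 95% counting interval 16.7 to 33.8; adjusted p = 1.45e-05). Genes of the medial ganglionic eminence lineage were higher for 9 of 10 and lower for 0 (camera adjusted p = 1.02e-20, 2.55e-05 with an estimated correlation), with Lhx6 at 4.32 ± 0.28 and the transcription factor gene Tox at 3.27 ± 0.30. Reln, which encodes the secreted glycoprotein reelin, rose by 3.78 ± 0.16, and Calb1, the calbindin gene, by 4.25 ± 0.22.

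The largest fold change in SST belonged to Myh13, a myosin heavy chain gene (544791, chromosome 11, 67327103 to 67371587), with 22.8 ± 7.83 CPM in SST and 4 reads over PV and VIP (ratio 326, 95% counting interval 127 to 1200; adjusted p = 8.42e-12). Otof, which encodes the calcium sensor otoferlin, had 17.0 ± 10.8 CPM (ratio 131, 59.9 to 357), Dlk1, a Notch pathway ligand, 36.0 ± 10.3 (18.3, 15.1 to 22.5), Adgrg6, an adhesion receptor, 11.2 ± 4.05 (37.6, 22.7 to 67.5), Prlr, the prolactin receptor, 19.0 ± 5.50 (30.9, 22 to 44.8) and Epyc, a matrix proteoglycan, 11.5 ± 6.32 (32.8, 20.9 to 54.8). Ankrd63 rose by 6.14 ± 0.42 to 34.4 ± 20.5 CPM. Like the striatal markers described below, Otof and Ankrd63 were highest in SST replicates 3 and 1 and lowest in replicate 4. On the lower side, Col24a1, a collagen gene, fell by 5.62 ± 0.70 to 0.187 ± 0.112 CPM, Mybpc1 fell by 5.35 ± 0.51 to 0.905 ± 0.415, Itih5 fell by 4.78 ± 0.54 to 1.49 ± 0.749, Pde5a, a phosphodiesterase of cyclic GMP, fell by 4.11 ± 0.32 to 6.99 ± 1.66 and Aebp1 fell by 3.77 ± 0.48 to 1.17 ± 0.806. Vip fell by 4.87 ± 0.78, Pvalb fell by 1.40 ± 0.39 (adjusted p = 0.0112) and Gad1 fell by 0.63 ± 0.17 (adjusted p = 0.00802), while Gad2 rose by 0.79 ± 0.18 (adjusted p = 0.00171).

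Neuropeptide precursor genes were higher in SST for 11 of 21 and lower for 3 (camera adjusted p = 7.29e-05, 0.025 with an estimated correlation), with the neurotensin gene Nts at 5.22 ± 0.52. Neuropeptide receptor genes were higher for 15 of 26 and lower for 4, and 15 and 6 when adjusted over the list alone (camera adjusted p = 1.05e-08, 0.0013 with an estimated correlation). Oprk1, the kappa opioid receptor gene that responds to dynorphins, rose by 4.52 ± 0.46, and Sstr1, a somatostatin receptor gene, by 3.92 ± 0.26. Genes for AMPA, NMDA, kainate and delta glutamate receptors were higher for 6 of 16 and lower for 2 (camera adjusted p = 6.43e-05, 0.0118 with an estimated correlation), with the NMDA receptor subunit gene Grin3a at 3.87 ± 0.21. Metabotropic glutamate receptor genes were higher for 4 of 7 and lower for 0 (camera adjusted p = 3.13e-05, 0.00157 with an estimated correlation). Calcium channel genes were higher for 9 of 15 and lower for 1 (camera adjusted p = 2.8e-06, 0.0126 with an estimated correlation), with Cacna2d3 at 2.19 ± 0.15. Presynaptic release genes were higher for 15 of 31 and lower for 2 (camera adjusted p = 1.09e-07; adjusted p = 0.0646 with an estimated correlation), with the vesicle priming gene Unc13c at 3.90 ± 0.34. Gabrg1, a GABA-A receptor subunit gene, rose by 4.19 ± 0.41.

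All 9 measured striatal neuron markers were higher in SST (camera adjusted p = 5.39e-17, 0.00157 with an estimated correlation). The adenosine receptor gene Adora2a rose by 5.15 ± 0.48 and the dopamine receptor gene Drd2 by 4.46 ± 0.48. Their summed level averaged 880 ± 461 CPM in SST, with a range of 400 to 1494, against 122 to 188 CPM in the other 18 libraries. Pan-GABAergic markers were lower for 5 of 15 and higher for 1 (camera adjusted p = 0.00774, 0.147 with an estimated correlation). Excitatory neuron markers were higher for 14 of 19 and lower for 0, and 15 and 1 when adjusted over the list alone (camera adjusted p = 1.23e-11, 0.025 with an estimated correlation). Slc17a7 rose by 1.83 ± 0.40 (adjusted p = 0.00124), Slc17a6, which encodes VGLUT2, by 3.35 ± 0.40 and the transcription factor gene Foxp2 by 4.91 ± 0.31. Foxp2 and the striatal sum were both highest in SST replicates 3 and 1 and lowest in replicate 4. The 2 female SST libraries, replicates 4 and 6, had striatal sums of 400 and 449 CPM, against at least 773.5 CPM in the 4 male ones. Foxp2, Otof and Ankrd63 were also lower in both female libraries than in every male one. A link to sex within SST was not tested for these genes as a group. Whether Foxp2, Otof and Ankrd63 share a source with the striatal markers was not tested. Markers of cortical layers 5 and 6 were higher for 7 of 13 and lower for 1 (camera adjusted p = 7.13e-08, 0.00362 with an estimated correlation). Astrocyte markers were lower for 6 of 12 and higher for 0, and lower for 9 when adjusted over the list alone (camera adjusted p = 0.000238; adjusted p = 0.249 with an estimated correlation); Aqp4 fell by 2.45 ± 0.66 (adjusted p = 0.00879). With the pool as a covariate 1 of the 12 astrocyte markers was lower, and their median was 0.47 instead of -1.45.

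In all, 2727 genes differed between SST and the mean of PV and VIP, 1662 higher and 1065 lower. DESeq2 called 3240 genes, 1630 higher and 1610 lower, so that the share of higher calls was 50.3% against 60.9%. With the sequencing pool as a covariate Chodl (1.67, adjusted p = 1), Mybpc1 (-4.77 ± 2.34), Pvalb (-0.32 ± 2.35) and Gad2 (0.17 ± 0.30) lost their calls and the fitted change of Aqp4 changed sign (0.49 ± 1.33).

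**Figure D4:**
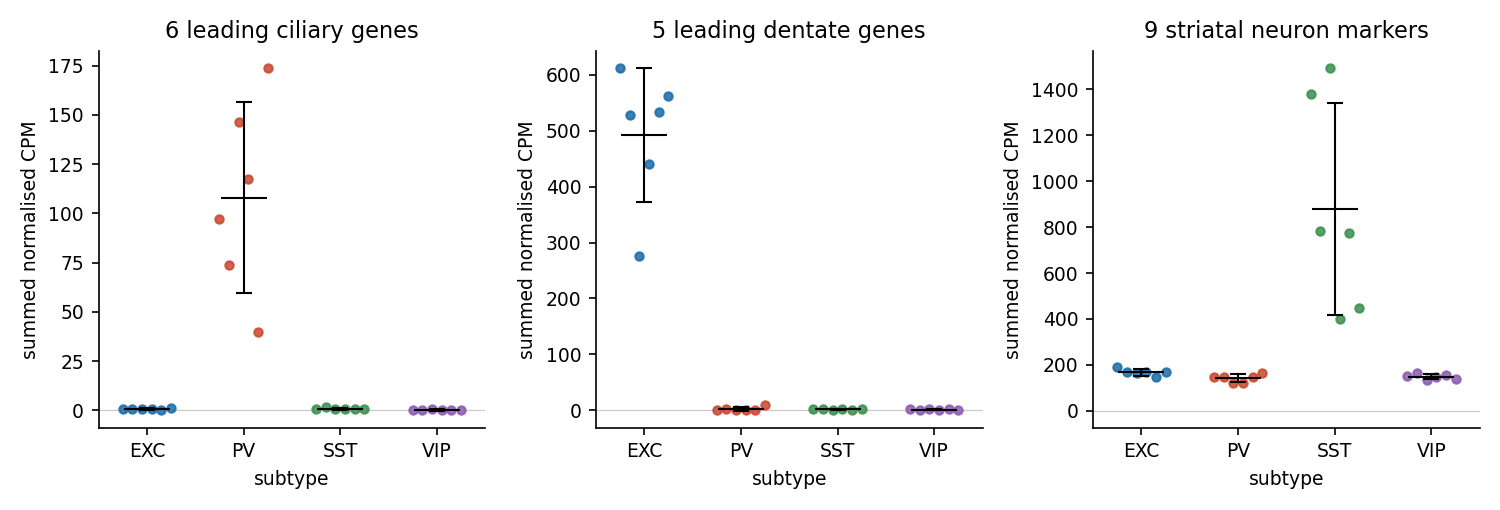
Summed normalised CPM of 6 leading ciliary genes, 5 leading dentate granule cell genes and 9 striatal neuron markers, with 1 point per library and the mean ± SD of 6 libraries per subtype. The ciliary genes averaged 108 CPM in PV, the dentate genes 492 CPM in EXC and the striatal markers 880 CPM in SST.

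VIP was compared with the mean of PV and SST. Genes of the caudal ganglionic eminence lineage stood higher in VIP, and genes of the medial lineage and of respiration lower than that mean. Vip rose by 10.69 ± 0.43 (adjusted p = 2.61e-16). All 14 VIP interneuron markers (camera adjusted p = 6.12e-39, 1.09e-06 with an estimated correlation) and all 10 genes of the caudal lineage (camera adjusted p = 1.34e-36, 1.09e-06 with an estimated correlation) were higher. Adarb2 rose by 8.31 ± 0.28 to 960 ± 252 CPM, Htr3a by 7.46 ± 0.35 to 132 ± 44.2 CPM, and the chemokine gene Cxcl14 by 6.73 ± 0.32. Prox1, a homeobox gene of the caudal lineage, rose by 7.0 ± 0.20 to 1130 ± 39.6 CPM; in EXC it stood at 942 ± 103 CPM. Prox1os, which overlaps it in the opposite direction, had 15.2 ± 3.18 CPM (ratio 155, 95% counting interval 80.9 to 340), but reads of the overlap cannot be assigned because the strand of the counts is not given in the sources used here. Calb2 rose by 5.56 ± 0.37.

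Chat, the acetylcholine synthesis gene (12647, chromosome 14, 32408203 to 32465909), had 15.5 ± 4.58 CPM in VIP and 1 read over PV and SST (ratio 1400, 95% counting interval 250 to 55200; adjusted p = 9.53e-10). Slc18a3, the vesicular acetylcholine transporter gene that lies within it, had 15.8 ± 5.60 CPM and 1 read (ratio 1440, 258 to 57100; adjusted p = 7.31e-10). Tac2 had 450 ± 137 CPM (ratio 68.2, 62.9 to 74.1; adjusted p = 7.07e-16), and Grpr, the receptor of gastrin-releasing peptide, rose by 7.42 ± 0.41 to 379 ± 106 CPM. Npy1r rose by 5.96 ± 0.25, the nicotinic receptor gene Chrna5 by 5.72 ± 0.41, the synaptic organiser Cbln2 by 5.54 ± 0.20 and Synpr, a synaptic vesicle protein gene, by 4.56 ± 0.23. Rag1, the recombination enzyme gene of lymphocytes, had 11.9 ± 3.47 CPM in VIP (ratio 144, 72.4 to 335; adjusted p = 7.15e-09) and Sycp1, a meiosis gene, 11.8 ± 11.4 CPM (ratio 213, 90.7 to 660; adjusted p = 1.89e-08). Sycp1 ran from 2.76 CPM in VIP replicate 5 to 32.05 CPM in VIP replicate 1.

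Genes of the medial lineage were lower in VIP for 8 of 10 and higher for 2 (camera adjusted p = 7.97e-14, 0.00011 with an estimated correlation). Lhx6 fell by 7.80 ± 0.42 to 0.738 ± 0.646 CPM, the transcription factor gene Sox6 fell by 7.27 ± 0.51, and Nxph1, a secreted neurexin ligand, fell by 5.40 ± 0.38. PV interneuron markers were lower for 10 of 15 and higher for 3 (camera adjusted p = 3e-10, 0.00314 with an estimated correlation), and SST interneuron markers lower for 9 of 15 and higher for 2 (camera adjusted p = 6.33e-05, 0.015 with an estimated correlation). Oprd1 fell by 8.56 ± 0.43 to 0.190 ± 0.317 CPM, Moxd1 fell by 8.17 ± 0.52 to 0.251 ± 0.368, Tac1 fell by 7.51 ± 0.41 to 0.561 ± 0.537, Pvalb fell by 6.13 ± 0.43 and Sst fell by 5.91 ± 0.74. Akr1c18 had 0 reads in VIP against 389 over PV and SST, at least 55.3-fold lower against a floor of 3 counts over the group (adjusted p = 2e-05). Excitatory neuron markers were lower for 15 of 19 and higher for 0 (camera adjusted p = 3.42e-09; adjusted p = 0.0661 with an estimated correlation), and Slc17a7 fell by 1.96 ± 0.46 (adjusted p = 0.00128). Gad1 (0.28 ± 0.16, adjusted p = 0.152) and Gad2 (-0.14 ± 0.18, adjusted p = 0.549) did not pass the test.

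Nuclear oxidative phosphorylation genes were lower in VIP for 27 of 28, with a median of -1.03 (camera adjusted p = 2.99e-09; adjusted p = 0.272 with an estimated correlation); Ndufb5 fell by 1.45 ± 0.22 and Ndufa4 fell by 1.34 ± 0.21. That mean includes PV, the subtype with the highest level of these genes: between SST and VIP alone 7 of 28 were called, all higher in SST (median 0.51), and 17 within POOL7098 (median 0.90). Within POOL7098 the VIP side is replicates 1 and 3 only. VIP replicates 1 and 6 had the lowest sums of these genes in VIP (1809 and 2269 CPM) and the lowest mitochondrial shares (1.80% and 4.81%). They also had the highest levels of Malat1 and Meg3 in VIP. What links these values was not tested. Perineuronal net and matrix genes were lower for 7 of 14 and higher for 3 (camera adjusted p = 0.00124; adjusted p = 0.0503 with an estimated correlation); Mme fell by 4.41 ± 0.25 and Acan fell by 4.17 ± 0.73. Voltage-gated potassium channel genes were lower for 21 of 35 and higher for 9 (camera adjusted p = 0.00532; adjusted p = 0.273 with an estimated correlation); Kcnh5 fell by 3.11 ± 0.25 and Kcns3 fell by 2.82 ± 0.36. The calcium channel subunit gene Cacna2d2 fell by 3.66 ± 0.22. Cholesterol synthesis genes were higher for 9 of 19 and lower for 0 (camera adjusted p = 0.0537), with the enzyme genes Msmo1 at 1.48 ± 0.23 and Lss at 1.08 ± 0.18.

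In all, 6899 genes differed between VIP and the mean of PV and SST, 3843 higher and 3056 lower. With the sequencing pool as a covariate the count was 2627, of which 2152 had been called without it. In that fit Chat, Slc18a3, Sycp1 and Akr1c18 lost their calls (adjusted p = 1) although their fitted changes stayed large, at 6.85, 9.16, 7.32 and -5.90, and were left undetermined. Kcns3 (-2.22 ± 0.87), Ndufb5 (-0.69 ± 0.26), Ndufa4 (-0.64 ± 0.24) and Acan (-3.0 ± 1.21) lost theirs with smaller changes, Gad2 gained one (-0.73 ± 0.21, adjusted p = 0.0178), and 4 of the 28 oxidative phosphorylation genes were called lower.

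Between pairs of subtypes the test called 6841 genes for PV against EXC (3030 higher in PV, 3811 lower), 5723 for SST against EXC (2550 and 3173), 5821 for VIP against EXC (2735 and 3086), 3911 for PV against SST (1698 and 2213), 7242 for PV against VIP (3267 and 3975) and 4658 for SST against VIP (2168 and 2490). Against EXC, Slc17a7 fell by 4.77 ± 0.54 in PV (adjusted p = 5.36e-08), fell by 3.63 ± 0.49 in SST (adjusted p = 1.46e-06) and fell by 6.16 ± 0.57 in VIP (adjusted p = 1.38e-09). Gad1 rose by 3.67 ± 0.21 in PV against EXC (adjusted p = 1.46e-13). Pvalb rose by 7.20 ± 0.39 in PV against EXC (adjusted p = 7.24e-14), by 5.96 ± 0.35 against SST (adjusted p = 2.01e-12) and by 9.11 ± 0.45 against VIP (adjusted p = 1.33e-14). Sst rose by 5.50 ± 0.72 in SST against EXC (adjusted p = 7.8e-07) and by 8.0 ± 0.82 against VIP (adjusted p = 2.08e-08), and it fell by 4.18 ± 0.68 in PV against SST (adjusted p = 3.37e-05). Vip rose by 10.34 ± 0.57 in VIP against EXC (adjusted p = 8.77e-14), and it was lower in PV (0.756 CPM) than in VIP (1730 CPM; adjusted p = 2.89e-13) and fell by 10.37 ± 0.56 in SST against VIP (adjusted p = 1.09e-13). With the pool as a covariate the counts were 6684 for PV against EXC, 4874 for SST against EXC, 3714 for VIP against EXC, 3259 for PV against SST, 2341 for PV against VIP and 4551 for SST against VIP. Of these, 6174, 2459, 2113, 1082, 1331 and 3599 had been called without it. The share of higher calls went from 44.6% to 54.9% for SST against EXC and from 47% to 54% for VIP against EXC. It went from 43.4% to 33.8% for PV against SST and from 45.1% to 32.6% for PV against VIP. For PV against EXC it went from 44.3% to 45.2%, and for SST against VIP from 46.5% to 49.3%. In that fit the fitted change of Slc17a7 in SST against EXC changed sign, and Pvalb in PV against SST lost its call (4.86 ± 2.26, adjusted p = 0.127).

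Pools allowed 2 of these comparisons within a single pool. In POOL6188, with 6 PV and 5 EXC libraries, 5685 genes differed. There 27 of 28 nuclear oxidative phosphorylation genes were higher in PV, all 15 pan-GABAergic markers were higher and 17 of 19 excitatory markers were lower. In POOL7098, with 5 SST and 2 VIP libraries, 6868 genes differed. There all 9 striatal markers were higher in SST, 14 of 15 SST interneuron markers were higher and 13 of 14 VIP interneuron markers were lower. PV with SST, PV with VIP and SST with EXC never shared a pool, so subtype and pool cannot be told apart within a pool for these pairs. VIP and EXC shared POOL7099 through EXC replicate 3 only, and no test was run there.

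Female and male libraries were compared across the 4 subtypes. The test called 6 genes, all on the sex chromosomes, with 2 higher and 4 lower in females, and 392 genes had an unadjusted p under 0.05. Xist, the RNA that silences the inactive X chromosome (213742, chromosome X, 103460373 to 103483233), averaged 2460 ± 2200 CPM in the 11 female libraries and 14.5 ± 21.8 CPM in the 13 male ones (log2 fold change 6.99 ± 0.60 SE, adjusted p = 1.55e-08). Tsix, which overlaps Xist in the opposite direction, rose by 7.05 ± 0.49 (adjusted p = 2.21e-10); without the strand of the counts the reads of Xist and Tsix cannot be told apart. Ddx3y, a Y-linked RNA helicase gene (26900, chromosome Y, 1260715 to 1286628), averaged 77.2 ± 44.2 CPM in males and 0.223 ± 0.327 CPM in females. On the log2 scale Ddx3y fell by 9.37 ± 0.37 in females (adjusted p = 8.61e-16), Kdm5d fell by 9.03 ± 0.37, Uty fell by 9.40 ± 0.40 and Eif2s3y fell by 9.64 ± 0.60. All 13 male libraries had at least 26.2 CPM of Ddx3y and all 11 female ones at most 1.07 CPM. Of 10 measured X inactivation and escape genes, 1 was higher, and 4 when adjusted over the list alone (camera adjusted p = 6.52e-12, 4.66e-05 with an estimated correlation). Nuclear oxidative phosphorylation genes (camera adjusted p = 1.45e-06, towards females; adjusted p = 0.79 with an estimated correlation) and immediate early and stress genes (camera adjusted p = 7.65e-05, towards males; adjusted p = 0.406 with an estimated correlation) had 0 members past the test of single genes in edgeR. A test for sex differences that vary between subtypes called 0 genes in edgeR after the filter on low counts, with 319 genes at an unadjusted p under 0.05, against 1 gene in DESeq2 and 88 in edgeR without that filter.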

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

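No test in this part was chosen for a single result after it was seen; the search for libraries far from the rest of their group was applied to every group of 6 libraries whose values are reported. It covered 122 groups and found such a library in 14. For independent, normally distributed values chance alone would find about 1 in 20 groups, or 6.1. Some levels lie near 0 and the groups share libraries, so 14 against 6.1 does not measure an excess over chance. After the filter on low counts no sex difference between subtypes was called in edgeR, with 319 genes at an unadjusted p under 0.05; DESeq2 called 1 gene, and edgeR without that filter called 88.

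EXC replicate 5 had 16736 genes with at least 1 read, against 18936 to 20182 in the other 5 libraries. The summed level of astrocyte markers in EXC replicate 6 was 4695 CPM, against 829 to 2013. Btbd11 stood at 1.36 CPM in EXC replicate 2, against 3.4 to 3.97. EXC replicate 3 had 19.9 CPM of Ccnjl, against 8.24 to 11.9, and 29.6 CPM of Robo3, against 3.83 to 12.3. Gjd2 stood at 2.22 CPM in EXC replicate 4, against 0.132 to 0.851. Itih5 stood at 2.97 CPM in SST replicate 1, against 0.891 to 1.51. VIP replicate 5 had 24.1 CPM of Slc17a7, against 0.719 to 8.22, and 17.7 CPM of Sst, against 0.12 to 3.87.

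The remaining 5 rest on 1 library with reads where the others of its subtype had 0. They are Lrrc38 in EXC replicate 4 (0.391 CPM), Plpp4 (0.747 CPM) and Stk26 (0.747 CPM) in PV replicate 1, Tac2 in PV replicate 5 (0.218 CPM) and Ttr in PV replicate 4 (68.8 CPM). Plpp4, Stk26 and Tac2 had 1 read each over the 6 PV libraries and Lrrc38 had 3 over the 6 EXC libraries.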

How the results depend on the processing

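The fits without mitochondrial genes, without EXC replicate 3 or 6 and without PV replicate 1 or 6 were chosen only after the data were seen; the other alternatives were planned. No paired analysis was possible because the labels pair no libraries and the replicate numbers follow the order of deposition.

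The counts of called genes for the subtype comparisons stayed within 1.5 times their value under all alternatives, with 4 exceptions, all with the pool as a covariate. In that fit 2729 genes were called for PV, 2627 for VIP, 3714 for VIP against EXC and 2341 for PV against VIP. Of the genes called without the covariate, it called 3679 again for EXC, 1149 for PV, 1452 for SST and 2152 for VIP. Over all alternatives the counts ran from 5479 to 7597 for EXC, from 2729 to 7063 for PV, from 2436 to 4018 for SST and from 2627 to 7610 for VIP. No scaling moved the median log2 fold change of all genes by more than 0.1 in the 4 main comparisons. Only 1 EXC library lies outside POOL6188, so with the pool in the model PV is tied to the other sorts through EXC replicate 3. That library is unusual for EXC, with 3049 CPM of excitatory markers against 5841 CPM or more in the others. Why the counts moved beyond that was not separated, and the cause was not tested.

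For sex, leaving out genes on X and Y gave 0 genes in edgeR, by construction of a test whose calls all lay there. The test of sex differences between subtypes called 1 gene in DESeq2 and 88 without a filter on low counts, against 0 in the other fits; the cause was not tested. Of 37 lists camera called 12 for EXC, 20 for PV, 21 for SST and 12 for VIP. With an estimated correlation these counts were 6, 7, 13 and 5, and fry called 28 for EXC and 25 for VIP; the cause was not tested.

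Of 170 gene values, the pool covariate left 126 on the same side of the threshold with the same direction, took 36 calls away, added 2 and changed the sign of 6. The fitted changes became -2.12 for Mobp in EXC, -3.42 for Slc17a7, 0.55 for Gad2 and -1.85 for Cox6a2 in PV, 0.49 for Aqp4 in SST, and 0.74 for Slc17a7 in SST against EXC; the cause was not tested. With only the libraries compared, 1 gene gained a call, Gad1 in PV (adjusted p = 0.0444 in edgeR). Robust empirical Bayes, leaving out EXC replicate 3 and leaving out EXC replicate 6 each took away 1 call, that of Sst in EXC. Under the other alternatives every gene value that could be computed kept its direction and its side of the threshold.

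Of the lists called by camera the pool covariate changed the sign of the median for 0 of 12 in EXC, 4 of 20 in PV, 2 of 21 in SST and 0 of 12 in VIP. In PV these were layer 2/3 and 4 markers (0.80 to -0.05), astrocyte markers (0.98 to -2.24), voltage-gated potassium channels (0.17 to -0.51) and nuclear oxidative phosphorylation genes (1.26 to -0.18). In SST they were astrocyte markers (-1.45 to 0.47) and nuclear oxidative phosphorylation genes (-0.22 to 0.63); the cause was not tested. Single libraries moved some gene lists. Without EXC replicate 3 the oligodendrocyte list in EXC reached a camera adjusted p of 0.00805, against 0.11, and the neurogliaform and LAMP5 list in PV went from 0.035 to 0.211. Without PV replicate 1 the lists of oligodendrocyte precursors, AMPA receptor auxiliary subunits and cholesterol synthesis in PV went to 0.0505.

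Depth limits the genes near the floor. PV had the lowest totals, and a gene at 10 CPM has 15.5 reads in its shallowest library. In simulated data 48% of genes changed 2-fold were recovered for PV and 66% for SST. The genes changed there all lay above a minimum mean count, so these values do not cover genes near the floor. They came from different random genes and do not show an effect of depth.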

Other observations

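The tests of pool for the mitochondrial share and the oxidative phosphorylation genes, the test of pool for the dentate genes, the test of displacement and the test of RNA loss were chosen only after the result was seen, and the lists of ependymal, choroid plexus, dentate and hippocampal pyramidal genes were written after the leading genes were known.

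Several gene lists moved beyond those described above. Layer 2/3 and 4 markers were higher in SST for 5 of 11 genes and lower for 0 (camera adjusted p = 5.12e-05, 0.0377 with an estimated correlation), and neurogliaform and LAMP5 interneuron markers were higher for 4 of 9 and lower for 2 (2.17e-06, 0.0126). Receptors for acetylcholine and monoamines were higher in SST for 14 of 28 and lower for 4 (0.000658; 0.144 with an estimated correlation), and AMPA receptor auxiliary subunits for 9 of 17 and lower for 2 (9.52e-06; 0.0701). Synaptic adhesion genes were higher in VIP for 16 of 34 and lower for 6 (0.00864; 0.395). Striatal markers were lower in PV for 7 of 9 (0.015; 0.319), but the mean it was compared with includes SST at 880 CPM, and the other 18 libraries, PV among them, had 122 to 188 CPM. Cholesterol synthesis genes were lower in PV for 10 of 19 and higher for 1 (0.0291; 0.453). Of 8 hippocampal CA pyramidal genes, 7 were higher in EXC.

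Random assignment of labels was tested for 12 counts with 40 assignments each, including the real one. Only the real one, 1 of 40, reached its own count. That is the smallest share that 40 assignments can give, and the 12 tests were not adjusted for one another. It was not run for SST against VIP within POOL7098, which has 2 VIP libraries. The real counts and the highest of the other assignments were 6330 and 0 for EXC, 6091 and 481 for PV, 2727 and 0 for SST, 6899 and 2429 for VIP, 6841 and 1 for PV against EXC, 5723 and 0 for SST against EXC, 5821 and 821 for VIP against EXC, 3911 and 0 for PV against SST, 7242 and 1316 for PV against VIP, 4658 and 1595 for SST against VIP, 6 and 1 for sex, and 5685 and 2992 for PV against EXC within POOL6188. The test within POOL6188 holds the pool fixed. The other tests of subtype labels do not part subtype from pool. Below, a pool effect alone was tested for 3 patterns, and a pool effect on top of a subtype difference for the first only.

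The first pattern is the high mitochondrial share of PV together with its higher nuclear oxidative phosphorylation genes. A sequencing pool effect alone is argued against, since the 5 EXC libraries of POOL6188 had mitochondrial shares of at most 9.84% and a nuclear level among nuclear genes of at most 4830 CPM, against at least 14.4% and 8685 CPM in PV, and 27 of 28 genes were higher in PV within that pool. A pool effect on top of a lower level in EXC stays open against SST and VIP. With the pool as a covariate, linked through EXC replicate 3 alone, 1 of the 28 was called higher and 1 lower (median -0.18 instead of 1.26). EXC replicate 3 had the lowest nuclear level among nuclear genes of all 24 libraries, 1493 CPM, against 2965 to 4830 in the other EXC libraries. That fit therefore cannot part a pool effect from a trait of this 1 library. Mitochondrial reads displacing other genes would change all nuclear genes by one factor and are argued against, since 28 of 28 oxidative phosphorylation genes lay more than 2 SE above the median change of all nuclear genes in PV (-0.08), the lowest at 0.75. Loss of cytoplasmic RNA stays open: across the 6 PV libraries, all in POOL6188, the mitochondrial share and the nuclear level among nuclear genes had a Pearson r of -0.583 (exact permutation p = 0.221, adjusted over 3 relations 0.331), a Spearman rho of -0.6 (exact p = 0.242, adjusted 0.362) and an r of -0.512 without the 2 libraries farthest from the median share, and r ran from -0.88 to 0.155 without each library in turn, positive only without PV replicate 5; a difference between the subtypes themselves stays open as an untested explanation.

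The second pattern is the ciliary genes among the leading PV genes, for which ependymal cells in the sort are a candidate source. The summed level of the 6 leading genes followed that of the 11 measured further ependymal genes across the PV libraries, with a Pearson r of 0.97 (exact permutation p = 0.00139, the smallest the permutations can give; adjusted 0.00417), a Spearman rho of 1 (exact p = 0.00278, adjusted 0.00833) and an r of 0.96 without the 2 farthest libraries; all 6 are in POOL6188. The further genes summed to 210 ± 93.6 CPM in PV and at most 21.4 CPM in any other library, the most abundant being Rsph4a (53.9 ± 27.1 CPM in PV, at most 6.03 on average elsewhere), Hydin (36.5 ± 14.3, 1.84) and Rarres2 (24.9 ± 13.5, 3.69); 6 of the 11 reach 1 CPM in another subtype and 0 are on a list fixed before. Choroid plexus cells are argued against, with 0 of 6 measured genes higher in PV (Ttr adjusted p = 0.196 in edgeR, 11.5 ± 28.1 CPM, with reads in PV replicate 4 only), and so is the pool alone, since the leading genes summed to at most 1.01 CPM in the EXC libraries of POOL6188 and to at least 40 CPM in PV. The gate for reporter-positive cells would remove ependymal cells that lack the reporter, and neurons that express these genes stay open as an untested alternative.

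The third pattern is the dentate granule cell genes among the leading EXC genes. For the summed level of the 12 further genes the pool alone is argued against, for these genes only. In POOL6188 they summed to at most 645 CPM in the PV libraries, against at least 3105 CPM in the EXC libraries. The list was written from known markers after the data were seen. Markers also high in another sort, such as Prox1, Calb1 and Pdyn, were left out, though Stxbp6 was kept. That 12 of 12 were higher in EXC, and how far their sum lay below it in PV, was therefore set in part by the choice. Neither counts for granule cells, and the gap within POOL6188 does not speak to dentate markers left out of the list. Granule cells of the dentate gyrus in the sort stay open, since neither that count nor the relation across libraries can decide. The further genes were led by Rfx3 (1080 ± 311 CPM, at most 141 on average elsewhere), Sema5a (962 ± 270, 375) and Stxbp6 (544 ± 155, 454). Across the 6 EXC libraries the sums had a Pearson r of -0.0377 (exact permutation p = 0.953, adjusted 0.953) and a Spearman rho of 0.2 (exact p = 0.714, adjusted 0.714). Without the 2 farthest libraries r was -0.527. Without each library in turn r ran from -0.387 to 0.532. It was positive without EXC replicate 1 (0.121) and without EXC replicate 3 (0.532), which leaves the 5 libraries of POOL6188. The sum of the further genes varied little in EXC, from 3105 to 4134 CPM. A steady share of granule cells would thus leave little to correlate. All 12 further genes reach 1 CPM in another subtype, and 0 are on a list fixed before. The gate kept reporter-positive cells, so granule cells would pass it only with the reporter; no biological explanation was tested.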
